A study of Bos taurus with 10 samples.

How the data were processed

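The labels describe total RNA of bovine embryos made by in vitro fertilization and of adult bovine tissues, hybridised across species to a human expression array. The 3 embryo arrays formed a group, and the brain, heart, kidney, liver, lung, muscle and spleen arrays formed 7 groups of 1 array each. Groups came from the sample titles alone. The age of the embryos, their number and the composition of each pool were not used here, and whether the 3 embryo arrays are separate pools is unknown.

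The authors deposited 1 intensity per probe set and array, on a linear scale. The software, background correction and scaling behind these intensities are not given in the sources used here. Of 22283 probe sets, 10219 had a value on all 10 arrays and 12064 were blank on every array; the reason for the blanks is not given in the sources used here. The 2% trimmed means of the arrays differed 1.90-fold, above the limit of 1.5 fixed before the data were examined, so the arrays were quantile normalized rather than used as deposited. Quantile normalization forces a common distribution on every array, which hides any true difference in total signal. Median deposited intensities ran from 99.2 to 221. No depth applies to arrays, and their number limits the precision.

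Probe sets were named by the human gene symbols of the platform annotation. Of the 10186 probe sets analysed, after leaving out 33 manufacturer's controls, 8847 had 1 symbol, 479 had several and 860 had none; probe sets with several symbols were not used to name a gene. Of 4727 genes tested, 4483 symbols (94.8%) are also in the bovine RefSeq gene table. Bovine sequence can differ from the human probes, so a dim probe set may reflect a poor match as well as a low level, and levels of different probe sets were not set against each other. No genome build is named for these values, so no coordinates are given.

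Intensities were transformed to log2(intensity + 72), the offset being the median over arrays of the 25th percentile. Probe sets above their array's median on at least 3 of 10 arrays were tested, 6775 in all. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust settings, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The main test set the 3 embryo arrays against the 7 tissues. A fit with 8 groups, which takes its spread from the embryo arrays alone (2 residual degrees of freedom before moderation), gave embryos against each tissue, with a 2-fold limit as well. Gene lists (37 fixed before the data were examined, 34 with at least 5 tested genes) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, all from limma, using the brightest tested probe set of each gene. For a gene with several probe sets the brightest stands for it, and where another probe set of a named gene moved the other way or hardly moved, its values are given beside the gene.

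Genes named in the text followed a rule fixed in advance. It took the 10 largest rises and 10 largest falls among genes past the threshold and separated from every tissue, up to 4 genes of each list, 12 genes fixed whatever their result, and up to 4 genes restricted to each tissue or 10 to embryos. Tissue restriction used a ratio of at least 4 on normalised values with no test. Similarity was the Spearman correlation across the tested probe sets.

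Tests were tried on simulated data with known changes. With 67, 67 and 66 probe sets changed by 1, 2 and 3 log2, the main test recovered 33, 59 and 63 of them with 4 false calls, provided embryos otherwise sat at the adult mean. With embryos drawn like an additional tissue it made 470 false calls, while the averaged arrays made 6 and recovered 1, 28 and 46. The 8-group fit recovered 3, 31 and 49 with 2 false calls, in data where each tissue array was drawn with the embryo arrays' mean and spread. With 1 array per tissue, that assumption about the spread cannot be checked in the real data.

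Alternatives were the values as deposited, a common median, no offset and an offset 4 times larger, no filter and a filter at the 75th percentile, eBayes without trend and robust, averaged embryo arrays, the spread from embryo arrays alone, an exact permutation of the 120 splits, 1 probe set per gene, a 2-fold limit and each array left out in turn. Leaving out the third embryo array together with muscle, and taking the probe set with the widest spread per gene, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.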

Results

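RNA of bovine embryos made by in vitro fertilization (IVF, the fertilization of oocytes outside the animal) and RNA of adult bovine tissues were hybridised to a human expression array. Each bovine transcript was therefore read by probe sets designed for a human gene, and genes are named here by those human symbols. There were 3 IVF embryo arrays and 7 adult arrays, with 1 array each of brain, heart, kidney, liver, lung, muscle and spleen. Intensities were present for 10219 probe sets, the same ones on all 10 arrays, and 10186 of these were not manufacturer's controls. The median deposited intensity lay between 99.2 in liver and 221 in the third embryo array. The number of arrays limits the precision of every value. Each tissue had a single array, so the adult spread is the spread between tissues. Nothing in the labels says whether the 3 embryo arrays came from separate pools of embryos or from the same RNA, so the spread between them may be technical only. The p-values of the main test pool that spread with the spread between tissues, and those of the fit with 8 groups rest on it alone.

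Marker genes fixed for each tissue were most often brightest, among the 7 tissues, in the array that carried that tissue's label. Among marker probe sets above the 75th percentile of any adult array, 28 of 35 brain probe sets were highest in brain, 32 of 39 liver probe sets in liver and 22 of 28 heart probe sets in heart. Skeletal muscle markers were highest in muscle for 27 of 42 probe sets and in heart for 10. Lung markers were highest in lung for 12 of 20, kidney markers in kidney for 7 of 14 and spleen markers in spleen for 6 of 16. The ratio of the 5′ to the 3′ GAPDH control probe set, a measure of RNA integrity, was 0.461, 0.488 and 0.463 on the embryo arrays and 0.287 to 0.471 on the tissue arrays. The same ratio for ACTB was 0.566, 0.728 and 0.604 on the embryo arrays and ran from 0.311 in lung to 1.52 in muscle and 2.65 in heart. In heart the 5′ and 3′ ACTB probe sets read 236.8 and 89.4. Ratios above 1, there and in muscle, cannot be read as better RNA integrity. The 5′ control for small-subunit ribosomal RNA read 1594, 241 and 137 on the 3 embryo arrays, and 465 to 3003 on the tissue arrays.

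The title of the series sets embryos against adult tissues, and this was the main comparison. Among the largest differences, KRT8 rose and COL3A1 and NR3C1 fell in embryos. KRT8, a keratin of simple epithelia, read 1565 ± 331 (SD, n = 3) in embryos and 56.5 ± 84.2 (SD, n = 7) in tissues, and its log2 difference was 3.86 ± 0.41 (SE, limma adjusted p = 9.9e-05). COL3A1, a fibrillar collagen, read 40.1 ± 9.02 (SD, n = 3) in embryos against 1091 ± 560 (SD, n = 7) in tissues, a log2 difference of -3.22 ± 0.42 (SE, limma adjusted p = 0.000486). Of its 2 other probe sets, the first fell by 2.39 and the second read 174 in embryos and 198 in tissues, a log2 difference of -0.07. NR3C1, the glucocorticoid receptor, read 19.7 ± 4.32 (SD, n = 3) against 597 ± 175 (SD, n = 7), a log2 difference of -2.82 ± 0.25 (SE, limma adjusted p = 3.72e-05), and its other tested probe sets were lower too. All log2 differences here are on the log2(intensity + 72) scale, which understates the change of dim probe sets.

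The largest rise was that of SFN, an epithelial regulator of the cell cycle, at 4.24 log2. It was followed by NTNG1, a membrane-bound relative of the netrin axon guidance proteins, at 3.95, and then by KRT8. DLEC1 rose by 3.47, and its 3 probe sets read 827, 739 and 810 in embryos against 9.24, 6.57 and 3.36 in tissues. ATP1B3, a subunit of the sodium-potassium pump, rose by 3.21, SEPTIN11, a cytoskeletal septin, by 3.08, SLC22A8, an organic anion transporter, by 3.05, and MELK, a kinase active in dividing cells, by 3.05. The other SEPTIN11 probe set did not share the rise, at 124 in embryos and 150 in tissues. SOX2, a transcription factor of pluripotent cells, read 791 ± 205 (SD, n = 3) in embryos and 64.3 ± 138 (SD, n = 7) in tissues, among which brain was brightest. The largest falls after COL3A1 were those of AQP1, a water channel (-2.99, its other probe set -1.18 with limma adjusted p = 0.198), NR3C1, MBNL1, a splicing regulator (-2.68), DAZAP2 (-2.67) and COL1A1, a fibrillar collagen (-2.56). HEG1, a receptor of endothelial cells, fell by 2.51, IGFBP7, a secreted binding protein, by 2.41, PDE2A, a cyclic nucleotide phosphodiesterase, by 2.36, and ZBTB20, a transcriptional repressor, by 2.35. The 2 other COL1A1 probe sets read 113 and 272 in embryos against 145 and 151 in tissues, so its probe sets did not move together, and the other HEG1 probe set read 176 against 192.

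**Figure D1:**
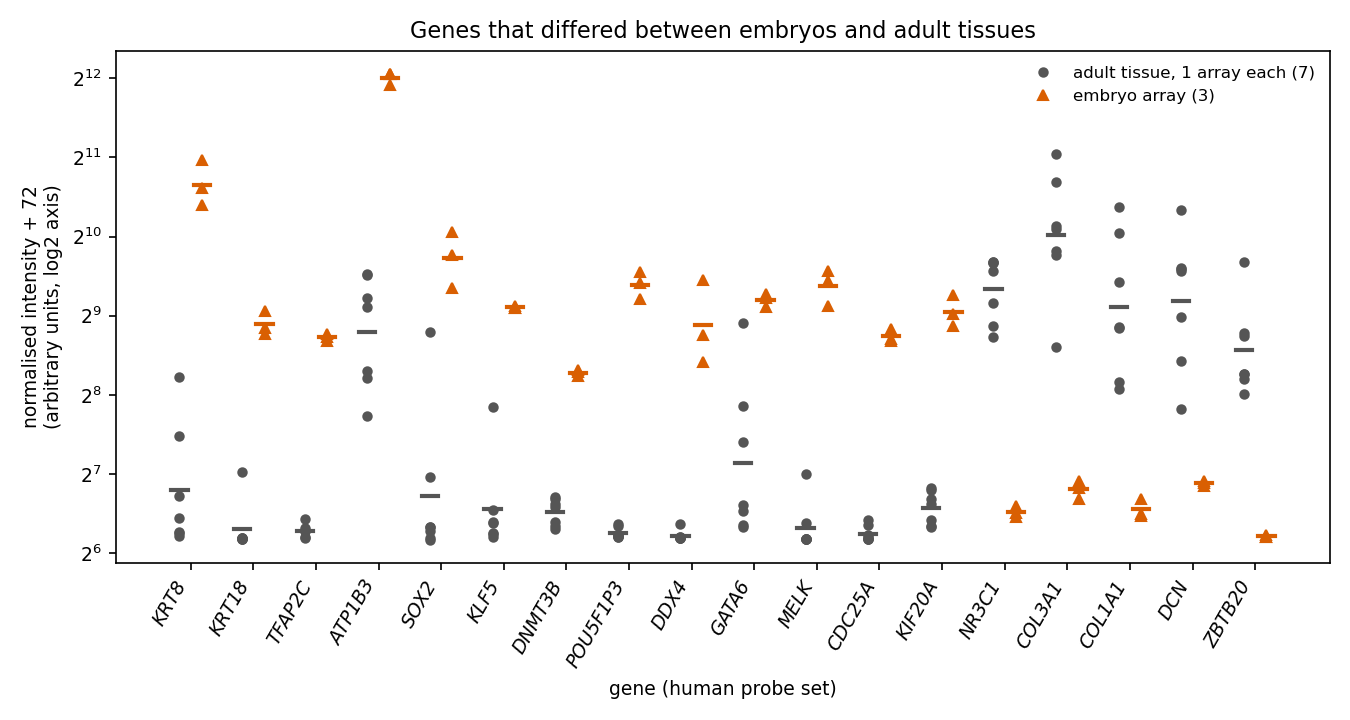
Quantile-normalised intensity plus 72 (arbitrary units, log2 axis) of 18 genes that differed between embryos and adult tissues, with 7 adult arrays as circles, 3 embryo arrays as triangles and the mean of the log2 values as a bar. KRT8 reads 1565 on average in embryos and 56.5 in tissues, and COL3A1 40.1 and 1091.

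Across the 6775 probe sets tested, limma called 601 higher and 218 lower in embryos after Benjamini-Hochberg adjustment at 0.05, or 73.4% of calls higher. At least 2-fold differences were called for 422 higher and 178 lower. With the values as deposited, 777 were higher and 151 lower, or 83.7% higher. Without any model of the spread, all 3 embryo values lay above all 7 tissues for 845 probe sets and below them for 448, where chance gives 56.5 in each direction (0.833% of those tested) if the 3 embryo arrays are independent, and up to 847 (12.5%) if they count as 1 sample. The mean of the embryo arrays lay above every tissue for 1223 and below every tissue for 818, so as 1 sample the embryo showed no excess of lower values. Nor can an excess of higher values be read from the 1223, since the filter was uneven between groups. Probe sets bright on the 3 embryo arrays alone were tested, while those bright in 1 tissue alone were not. Of the calls, 566 of the higher and 200 of the lower had all 3 embryo values outside the range of the 7 tissues. Where the 3 embryo arrays were averaged and counted as 1 sample, limma called 73 probe sets higher and 5 lower, all 78 of them also called above in the same direction, and 609 had an unadjusted p under 0.05. Named genes past the threshold in that fit were KRT8, KRT18, SFN, TFAP2C, DNMT3B, POU5F1P3, DDX4, CDC25A, KIF20A, MELK, DLEC1, NTNG1, SEPTIN11, SLC22A8, EIF1AY, FBL, SRSF5, NR3C1 and DAZAP2. Without the first, the second or the third embryo array, 83, 62 and 140 probe sets were called higher and 34, 27 and 44 lower. With an embryo array left out, the filter of at least 3 arrays passes no probe set bright in embryos alone. Part of this fall is therefore of probe sets that were not tested. In simulated data where embryos were drawn like an additional tissue, 73.8% of the calls of the 3-array test were false, against 7.41% with averaged arrays. These shares depend on how many changed probe sets were planted, and do not estimate the false share among the real calls.

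Some genes of the first cell lineages rose in embryos. Of 16 tested genes of the trophectoderm, the outer epithelium of the blastocyst, 5 rose, 1 fell and the others did not pass, and adjusted over the list alone 6 rose and 1 fell. KRT8 and ATP1B3 led this group, KRT18, the keratin partner of KRT8, rose by 2.59 and TFAP2C, a transcription factor of trophectoderm, by 2.44. The gene that fell was ATP1B1, a further pump subunit, at -1.94 (named after its values were seen). The limma camera test placed the list higher than other genes (adjusted p = 0.0105), with adjusted p = 0.167 with an estimated correlation. That call was lost without the first, the second or the third embryo array (camera adjusted p = 0.0855, 0.0880 and 0.181) and with no offset (0.0524). It was also lost without the third embryo array and muscle (0.288). With an embryo array left out, probe sets bright in embryos alone could not pass the filter.

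Of 11 tested pluripotency genes 3 rose and none fell, and adjusted over the list alone 4 rose. They were SOX2, KLF5 (2.56), a transcription factor of early embryo cells, and DNMT3B (1.76), a methyltransferase of new DNA methylation. The list did not pass camera (adjusted p = 0.0795, and 0.263 with an estimated correlation), with a median difference of 0.42. Camera called it without the lung array (median 1.57, adjusted p = 0.00705), without the liver array (1.10, 0.0337), without a filter on dim probe sets (0.0110) and with averaged embryo arrays (0.0429), and fry, which tests whether its genes move on balance in a single direction, gave adjusted p = 0.00152. POU5F1, the pluripotency factor also called OCT4, was read by a probe set whose human annotation lists 4 symbols, so by annotation alone it cannot be told from its human copies. That probe set read 521 ± 127 (SD, n = 3) in embryos and 9.16 ± 3.66 (SD, n = 7) in tissues. Probe sets assigned to the copies POU5F1P3, POU5F1P4 and POU5F1B rose by 3.14, 2.80 and 2.41, and are uncertain for the same reason. These copies are named from the human annotation, and whether bovine RNA holds them was not examined. Among 9 hypoblast genes, of the layer that forms the yolk sac, GATA6, a transcription factor (2.06), CTSV, a lysosomal protease (1.95), and FN1, fibronectin (1.66), rose and none fell, with 3 higher adjusted over the list alone and a camera adjusted p of 0.585. DDX4, a germ cell RNA helicase, rose by 2.66 and was the called gene among 3 tested oocyte genes, too few for a list test. NANOG, CDX2, DNMT1 and H19 were not analysed here because no intensity with their name was in the values used.

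Of 28 tested genes of mitotic cell division 16 rose in embryos and none fell, and adjusted over the list alone 18 rose and 1 fell. Beside MELK, the largest rises were those of CKS2 (2.55), a partner of cyclin-dependent kinases, CDC25A (2.49), a phosphatase that activates those kinases, and KIF20A (2.48), a kinesin of cytokinesis. CDC25A read 356 ± 22.8 (SD, n = 3) in embryos against 4.10 ± 5.50 (SD, n = 7) in tissues. The list had a camera adjusted p of 2.27e-10, and an adjusted p = 0.157 with an estimated correlation. DNA replication genes rose in 5 of 15 cases and none fell (7 higher adjusted over the list alone), among them RFC4, a clamp loader subunit (2.01), and PCNA, the sliding clamp (1.54). Their camera adjusted p was 0.00912, with adjusted p = 0.263 with an estimated correlation, and it was 0.0724 without the third embryo array. Of 32 genes of DNA methylation and chromatin, 11 rose and none fell (13 higher adjusted over the list alone), including NAP1L1, a histone chaperone (1.84), H2AZ1, a histone variant (1.64), and CHAF1A, a chromatin assembly factor (1.57). The other H2AZ1 and CHAF1A probe sets did not pass, at 1.02 and 0.77, nor did 1 of the 4 other NAP1L1 probe sets, at 0.50. This list had a camera adjusted p of 0.00141 and an adjusted p = 0.263 with an estimated correlation.

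Lists of protein production and protein turnover ranked higher than other genes by camera, although most members of most of them did not pass. Ribosome biogenesis genes rose in 7 of 13 cases, also adjusted over the list alone, among them FBL, a nucleolar methyltransferase (1.71), NCL, nucleolin (1.29), and NPM1, nucleophosmin (1.11), with camera adjusted p = 0.00462 and adjusted p = 0.157 with an estimated correlation. Translation factors rose in 9 of 38 cases (13 adjusted over the list alone), including EIF1AY (1.89), an initiation factor, and EIF4E2 (1.89), a cap-binding protein, with camera adjusted p = 0.00381 and adjusted p = 0.167 with an estimated correlation. Ribosomal protein genes rose in 3 of 52 cases (2 adjusted over the list alone), with camera adjusted p = 0.00912 and adjusted p = 0.666 with an estimated correlation, and fry did not call the list (adjusted p = 0.248). That camera call was lost without the brain array (camera adjusted p = 0.0601) and with arrays scaled to a common median (camera adjusted p = 0.0832). The 3 were RPS4Y1 (1.44), RPL14 (1.31, its other probe set 0.95 and not past the threshold) and RPL10A (1.09). RPS4Y1 and EIF1AY are Y-linked names whose X-linked copies could share their probes, so they are uncertain.

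Splicing genes rose in 7 of 49 cases (10 adjusted over the list alone), led by SNRPA1 (1.76), a spliceosome protein, and SRSF5 (1.62), a splicing regulator, with camera adjusted p = 0.00141 and adjusted p = 0.286 with an estimated correlation. Of 27 chaperone genes 9 rose and none fell (11 adjusted over the list alone). The chaperonin subunits CCT6A and CCT4 rose by 1.89 and 1.80 and DNAJA1, a co-chaperone, by 1.82, with camera adjusted p = 0.00778 and adjusted p = 0.238 with an estimated correlation. Proteasome genes rose in 8 of 28 cases and fell in 1 (13 and 1 adjusted over the list alone), with PSMG2, an assembly chaperone, at 1.38 and PSMC1, a base subunit, at -1.16. The proteasome list had a camera adjusted p of 0.00336 and an adjusted p = 0.263 with an estimated correlation.

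Matrix and fibroblast genes had the lowest camera p among the groups that were lower in embryos. Of 17 tested, 9 fell and none rose, and 11 fell adjusted over the list alone. DCN, decorin, a matrix proteoglycan, read 46.0 ± 2.77 (SD, n = 3) in embryos and 596 ± 352 (SD, n = 7) in tissues, although a further DCN probe set read 182 in embryos and 104 in tissues. The list's camera adjusted p was 1.98e-07, with adjusted p = 0.208 with an estimated correlation. Imprinted genes fell in 4 of 10 cases, also adjusted over the list alone: DCN, which both lists hold, GNAS, a signalling G protein subunit (-1.58), NNAT, neuronatin (-0.90), and CDKN1C, an inhibitor of the cell cycle (-0.71). The other CDKN1C probe set read 121 in embryos and 141 in tissues. Camera gave this list an adjusted p of 0.00912, with adjusted p = 0.167 with an estimated correlation. IGF2R, an imprinted growth factor receptor, did not pass (-0.76, limma adjusted p = 0.173).

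Lists of fatty acid oxidation, MHC and complement genes ranked lower than other genes by camera while no single member of them passed, either over all probe sets or adjusted over the list alone. For 14 fatty acid oxidation genes the camera adjusted p was 0.00912, with adjusted p = 0.482 with an estimated correlation, and fry did not call the list (adjusted p = 0.205). ACAA2, a mitochondrial thiolase, had the largest difference there, at -2.02 (limma adjusted p = 0.0839, named after its values were seen). For 11 MHC genes the camera adjusted p was 0.0492, with adjusted p = 0.53 with an estimated correlation, and for 8 complement and coagulation genes it was 0.0256, with adjusted p = 0.167 with an estimated correlation. Fry called the complement list (adjusted p = 0.00454) and not the MHC list (0.212). The MHC call was lost in the leave-outs of kidney, liver, lung, spleen and the first and the third embryo array (adjusted p = 0.113, 0.192, 0.217, 0.377, 0.0628 and 0.0954), and at a common median (0.0586), with an offset 4 times larger (0.0889) and with averaged embryo arrays (0.0608). With the probe set of widest spread per gene the MHC call was lost as well (camera adjusted p = 0.0957). The complement call was lost without kidney, liver, lung, spleen or the first embryo array (adjusted p = 0.0616, 0.145, 0.0622, 0.0635 and 0.0689).

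Camera called no list of the granulosa, endothelial, macrophage, smooth muscle or blood markers. The 8 granulosa and cumulus genes, of the cells around the oocyte, held none that passed (camera adjusted p = 0.896), and 4 sperm and 4 lymphocyte genes, too few for a list test, held none either. Endothelial markers held 1 of 10 that fell, AQP1, and 8 macrophage and 8 smooth muscle genes held none. The smooth muscle list was called lower with the values as deposited (camera adjusted p = 0.0438) and without the brain array (0.0355). HBB, a beta globin, rose by 1.68 and was the called gene among 6 blood genes, but its other probe sets read 57.4 and 312 in embryos against 157 and 73.9 in tissues. Glycolysis (12 genes) and apoptosis (16 genes) held no gene that passed, and oxidative phosphorylation (50 genes) held COX7A2, a cytochrome oxidase subunit, at 1.12, and its list was called higher without the heart array (camera adjusted p = 0.0119). In the oxidative stress list, PRDX2 (2.17) and PRDX1 (1.35), peroxide-reducing enzymes, and TXN, thioredoxin (1.09), rose while MGST3, a glutathione transferase, fell by 1.70, out of 17. The sterol synthesis enzymes NSDHL (1.42) and HMGCS1 (0.96) rose out of 6, and fry called their list (adjusted p = 0.00217) while camera did not (0.145). Counts adjusted over the list alone were the same for each tested list of this paragraph. The filter left 13 of 37 brain, 6 of 22 heart, 8 of 16 kidney, 14 of 42 liver, 8 of 15 lung, 8 of 38 skeletal muscle and 9 of 15 spleen markers in the test, and removed markers bright in fewer than 3 arrays. Camera called none of the 7 lists so reduced, while fry called the skeletal muscle list lower (adjusted p = 0.0105), and without a filter on dim probe sets camera called the heart (adjusted p = 0.0380) and skeletal muscle (adjusted p = 0.00961) lists lower. In the lung list PDPN, an epithelial glycoprotein brightest in lung among tissues (553), rose by 2.78 and AGER, a receptor, fell by 1.40. In the muscle list CACNG1, a calcium channel subunit, fell by 1.47, and in the kidney list SLC22A8 rose and AQP1 fell. AGER read 602 in muscle and 326 in lung, CACNG1 read 276 in liver and 15.6 in muscle, its lowest tissue, and SLC22A8 read 68.8 in lung and 3.67 in kidney, so these 3 probe sets did not act as markers of their tissue here. GAPDH and ACTB, often used as reference genes, did not pass (limma log2 differences of -0.27, adjusted p = 0.798, and 0.70, adjusted p = 0.406). Camera called 10 lists higher and 5 lower of 34 tested, and 0 with an estimated correlation, where the lowest adjusted p was 0.157; fry, which compares no list with other genes, called 11 higher and 4 lower.

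**Figure D2:**
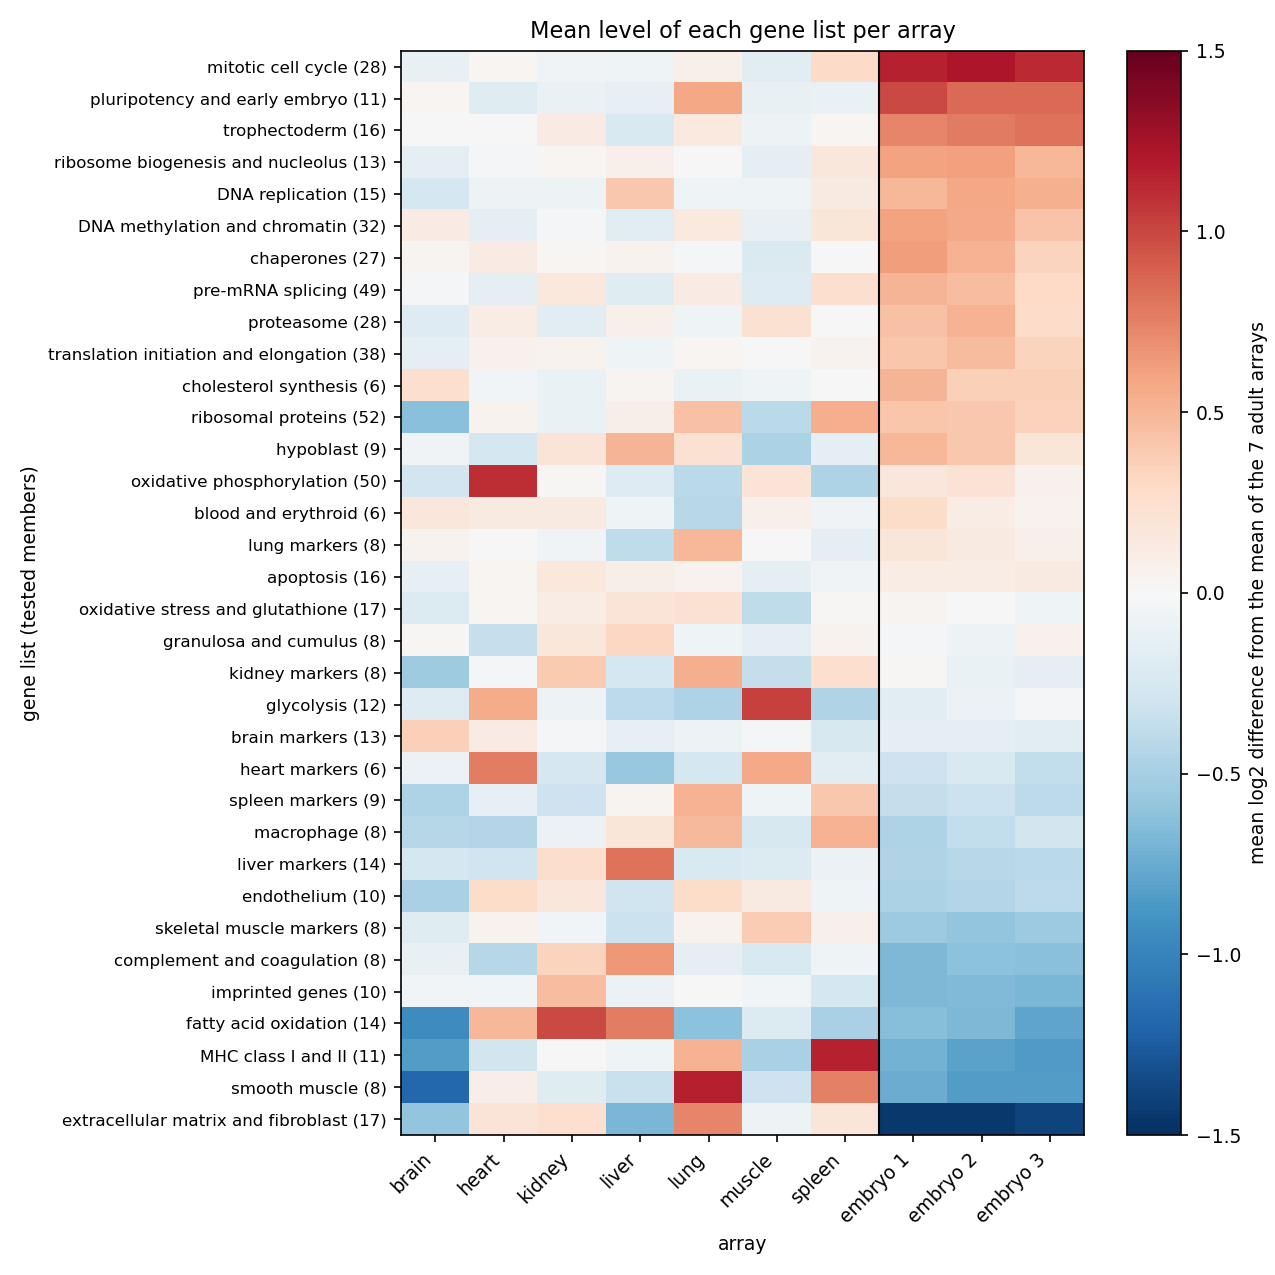
Mean log2 difference from the mean of the 7 adult arrays (colour, no further unit) for the tested members of each gene list, with arrays in columns and lists in order of their embryo mean; the black line parts the 7 adult from the 3 embryo arrays. The 28 mitotic genes average 1.16, 1.21 and 1.11 on the embryo arrays, and the 17 matrix genes -1.44, -1.45 and -1.39.

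Set against each tissue alone, embryos differed from muscle in 1533 probe sets, 1002 of them higher in embryos and 531 lower. Differences from heart numbered 1486 (827 higher, 659 lower), from brain 1380 (805 and 575) and from liver 1298 (895 and 403). Kidney gave 1139 (570 and 569), lung 1099 (556 and 543) and spleen 882 (411 and 471). These counts are probe sets with at least a 2-fold difference and limma adjusted p at most 0.05 in a fit with 8 groups, where each tissue's single array was assumed to vary like the embryo arrays. The filter was uneven here as well. Probe sets bright on the embryo arrays alone were tested, while those bright in the compared tissue alone were not. The lower counts therefore leave out probe sets of that kind, and the higher and lower counts cannot show which direction prevailed. The differences between these counts were not tested. Without the second embryo array the counts were 742 for muscle, 690 for heart, 612 for brain, 337 for liver, 314 for kidney, 344 for lung and 236 for spleen.

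Of the genes restricted to a single tissue, the tissue's fixed marker list held 11 of 79 in brain, 4 of 26 in heart, 0 of 8 in kidney, 18 of 150 in liver, 3 of 21 in lung, 8 of 34 in muscle and 3 of 9 in spleen. In brain these were GPM6B, SNAP25, GPM6A, SYT1, SYP, STMN4, CHN1, GAP43, VSNL1, NEFM and NEFL, named after their values were seen. TNNI3, cardiac troponin I, read 2773 in heart, at least 19 times any other group, and ACTC1, cardiac actin, read 1658 there, at least 11.4 times. SFTPC, a surfactant protein, read 3989 in lung and was at least 27.4 times higher there. TNNC2, a fast-muscle troponin, read 2157 in muscle, at least 14.8 times, and MYF6, a muscle transcription factor, read 1912, at least 12.7 times. PDZK1, a scaffold protein of kidney tubules, read 1143 in kidney (at least 7.84 times), and the spleen array held LCK, a T cell kinase (778, at least 5.34 times), and VCAM1, an adhesion molecule (705, at least 4.84 times). The genes with the highest ratio in the tissues other than heart were outside these lists. They included ISL1, a transcription factor of motor neurons, in brain, LHX1, a transcription factor of kidney development, in liver and L3MBTL1, a chromatin protein, in kidney, each at 8428 and at least 57.8 times any other group. Quantile normalization gives the brightest probe set of every array a common value, so these readings are equal by construction. AMT, an enzyme of glycine breakdown, led in lung (6224, at least 39.6 times), PRKAA1, a kinase subunit, in muscle (6224, at least 42.7 times) and GALR2, a galanin receptor, in spleen (1159, at least 7.95 times).

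By this rule, a value above the array's 75th percentile and at least 4 times every other group after raising those to their array's median, 182 probe sets were restricted to liver, 91 to brain, 40 to muscle, 33 to heart, 31 to lung, 26 to embryos, 11 to spleen and 10 to kidney. For embryos all 3 arrays had to pass the percentile and their mean entered the ratio, while a tissue needed 1 array. Counting only genes with 1 symbol, each at its brightest probe set, the 26 embryo probe sets were led by SFN (at least 12.2 times), NTNG1 (11.3), SEPTIN11 (6.86), KRT8 (6.85), ATP1B3 (6.06) and DLEC1 (5.67). TPM4, a tropomyosin (4.90), SINHCAF, a chromatin complex subunit (4.50), SLC22A8 (4.38) and POU5F1P3 (4.13) followed. With 1 array per tissue these are descriptions with no replicate check, and with the values as deposited the count was 110 for liver, also 110 for brain, 16 for heart, 6 for kidney and 7 for spleen. Where a restricted gene had a second probe set, that probe set was highest in the same group for 19 of 29 brain genes, 20 of 54 liver genes and 5 of 7 embryo genes. It was so for 3 of 7 heart genes, 4 of 16 muscle genes, 1 of 9 lung genes, 0 of 2 kidney genes and 0 of 3 spleen genes. In these 5 tissues together that was 21.6% of 37 genes (95% exact interval 9.83 to 38.2). An equal share among the 8 groups, 12.5%, lies within this interval. Of all analysed probe sets, 8.71% were highest in lung and 15.9% in muscle, the lowest and highest such shares of the 5.

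Embryo arrays resembled each other more than they resembled any tissue. The mean Spearman correlation across probe sets, which are not independent replicates, was 0.860 ± 0.0621 (SD over 3 pairs) between embryo arrays, 0.348 ± 0.0724 (SD over 21 pairs) between embryos and tissues and 0.496 ± 0.103 (SD over 21 pairs) between tissues. Spleen was the tissue closest to embryos at 0.456, followed by lung (0.385), liver (0.374) and kidney (0.374). Brain (0.310), muscle (0.270) and heart (0.269) were farther away. Lung and spleen, at 0.724, were the most alike pair of tissues, and heart and muscle reached 0.680. No test was made of these correlations, since pairs share arrays. Without a filter on dim probe sets the value between embryos and tissues was 0.504 and that between tissues 0.519, so most of the gap between these values was absent there, while embryo arrays reached 0.885 with each other.

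**Figure D3:**
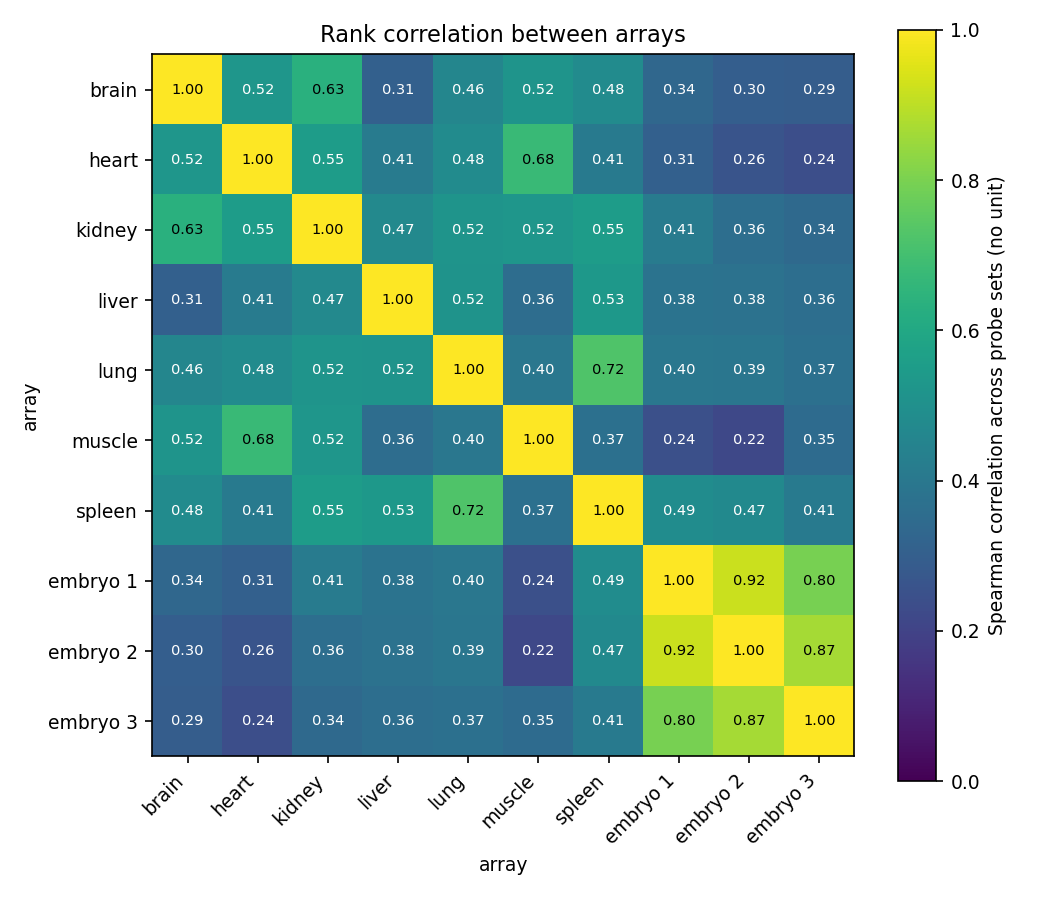
Spearman correlation across probe sets (colour and printed values, no unit) for each pair of the 10 arrays, with tissues first and embryo arrays last. The 3 embryo arrays form a bright block of mean 0.860, apart from the tissues at a mean of 0.348.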

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

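Of the tests in this part, that of muscle RNA in the third embryo sample and those of second probe sets outside the marker lists were chosen only after their results were seen. Over 40 measures of the 7 adult arrays, 6 had an array whose gap to the nearest other array was over 0.568 of the whole range, where chance gives about 2. In lung the pluripotency list averaged 0.579 log2 above the adult mean, against 0.03 in the next array. In heart the oxidative phosphorylation list averaged 1.10, against 0.21 in muscle. In kidney the imprinted list averaged 0.464, and in brain the sterol synthesis list averaged 0.255. The chaperone list in muscle averaged -0.215, and the blood list in lung averaged -0.410. A pair of control probe sets, outside the genes analysed, also stood apart: a BioB control (bacterial biotin synthesis RNA added as a spike) read 255.4 in muscle and at most 35.6 elsewhere, and a lysine-gene control of Bacillus read 16220.7 in liver and at most 10.8 elsewhere. Other lysine-gene controls read 51.7 and 7.7 on the liver array, so they did not share that reading.

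The count of 819 probe sets called between embryos and tissues was reached by 1 of 100 splits of the 10 arrays into 3 and 7, the real split, and the highest of the others gave 122. For the gene lists the real split called 15 of 34, also reached by 1 of 100 splits, and the highest of the others called 12. By these counts chance can be excluded only as a random grouping of the 10 arrays. The real split alone keeps the 3 arrays of a kind together, and simulated embryos drawn like an additional tissue gave 470 false calls, above every other split, so the splits cannot exclude that calls came from 3 similar arrays set against single tissues. The exact permutation called 0 probe sets, with a smallest adjusted p of 0.0728.

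The third embryo array and the muscle array shared bright probe sets. Their deviations, from the other embryo arrays and from the other tissues, correlated at 0.360 across probe sets (Pearson), and 222 probe sets were raised at least 2-fold in both against 30.7 if independent. Muscle RNA in that embryo sample is argued against, since 38 probe sets at least 8-fold higher in muscle differed by a median of -0.0290 log2 between the third and the other embryo arrays, and the muscle transcript TNNC2 read 2157 in muscle and 9.91 there. If transcripts were present in both samples, second probe sets should follow, and those of the 71 genes that had one moved by 0.0281 of the first probe sets' median of 1.43. This low ratio cannot exclude such transcripts. First probe sets were picked for their rise, second ones were taken whatever their brightness, and no genes known to differ were set beside them. An array-level technical effect on single probe sets, which requires that ratio to be low, remains a candidate explanation, and transcripts present in both samples stay open.

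Most genes restricted to a tissue lay outside its fixed marker list, 132 of 150 in liver and 68 of 79 in brain. Second probe sets should peak in that tissue if these were transcripts of the tissue, and over all restricted genes of brain and liver together 47.0% of 83 did (95% exact interval 35.9 to 58.3), a share between what transcripts and spikes would give, which decides nothing for the pool. Outside the lists, transcripts of that tissue for most genes are argued against in liver (29.2% of 48, 17.0 to 44.1). They remain a candidate explanation in brain (60.9% of 23, 38.5 to 80.3). In heart, kidney, lung, muscle and spleen together the share was 20.6% of 34 (8.70 to 37.9), with 3 of 7 in heart. This cannot decide there, since these were 34 of the 37 genes with a second probe set. Too few known markers were left to show that second probe sets follow in these tissues. Spikes of single arrays alone are argued against in brain and liver, where the lower limits lie above the 13.5% and 14.7% of all probe sets that are highest there. Spikes of single arrays stay open in the other 5 tissues, where the lower limit lies below chance, and as part of the signal in brain and liver, since no tissue has a second array and the embryo arrays, whose replicates can show spikes, held 1, 4 and 28. On the liver array the lysine-gene control gave such a reading, not shared by other controls of its gene. As 1 control probe set, it does not tell how many restricted genes are spikes.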

How the results depend on the processing

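Of 79 named results and 34 gene lists, none that was called reversed under the alternatives in which it had a value; reversal was not counted for the other probe sets. Every alternative fixed beforehand was run. No paired analysis was possible because the groups share fewer than 2 replicate numbers, each tissue having 1 array. Leaving out the third embryo array together with muscle, and the widest-spread probe set per gene, were chosen after seeing the data. Apart from settings built to test fewer samples or genes, the cause of a change was not tested. The values as deposited moved the median of all probe sets to 0.22 log2 above the tissues, against 0.04 after quantile normalization, so differences with that setting are relative to 0.22.

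The 601 higher and 218 lower calls lay between 422 and 777 and between 148 and 270 in the settings of normalization, offset, filter, moderation and fold. The higher share of calls was 63.7% with no offset, 73.4% in the main test, 81.9% with an offset 4 times larger and 83.7% as deposited. Averaging the embryo arrays, which leaves fewer samples, gave 73 and 5, the spread from embryo arrays alone gave 1651 and 1284, and 1 probe set per gene, which tests fewer, gave 354 and 135. The exact permutation gave 0 and 0: 775 probe sets reached its smallest possible p of 0.00833, and the smallest adjusted p was 0.0728. Without the third embryo array and muscle the counts were 87 and 29. Leaving out each array gave 62 to 636 higher and 27 to 295 lower. The low values came from leaving out embryo arrays, where the filter passes no probe set bright in embryos alone. Probe sets above every tissue numbered 530 and below every tissue 231 at the 75th percentile filter, 244 below as deposited, and 439 to 685 below with each array left out. Of 79 named results, 22 kept their side of the threshold with averaged embryos and 57 were weaker; 75 kept it as deposited and 75 at a common median. Without the first, the second and the third embryo array, 61 still had a value, of which 24, 22 and 36 kept their side.

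With an offset 4 times larger the probe sets changed from each tissue were 452 for brain, 488 for heart, 373 for kidney, 371 for liver, 329 for lung, 509 for muscle and 294 for spleen. At the 75th percentile filter, which tests fewer, they were 983 for heart, 852 for liver, 711 for lung and 559 for spleen. Leaving out each embryo array gave 612 to 1343 for brain, 690 to 1411 for heart, 314 to 1077 for kidney, 337 to 1266 for liver, 344 to 1089 for lung, 742 to 1601 for muscle and 236 to 849 for spleen.

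Camera with an estimated correlation called 0 lists higher and 0 lower, and leaving out each array gave 3 to 6 lower lists against 5. With averaged embryo arrays the pluripotency list passed (adjusted p = 0.0429) and the MHC list did not (0.0608). Without a filter the pluripotency, heart and skeletal muscle marker lists passed (0.0110, 0.0380 and 0.00961). The median, mean and tests differed in sign for the glycolysis, oxidative stress, blood, granulosa, kidney and lung lists, none of which was called.

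Restricted probe sets, for brain, heart, kidney, liver, lung, muscle, spleen and embryos in turn, numbered 318, 225, 75, 592, 140, 197, 94 and 154 at a ratio of at least 2, and 22, 4, 4, 55, 14, 11, 0 and 4 at a ratio of at least 8. With the floor at the 25th percentile they numbered 179, 72, 26, 390, 60, 78, 18 and 52. As deposited they were 110 for brain, 16 for heart, 6 for kidney, 110 for liver and 7 for spleen, and at a common median 54 for heart. The mean correlation between embryos and tissues was 0.504 with no filter and 0.252 at the 75th percentile filter, and that between tissues 0.519 and 0.466. Signal over background may limit all of this, since how well probe sets near the offset of 72 keep their order was not measured.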

Other observations

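In this part, the counts with single embryo arrays and the leave-out of 100 probe sets were chosen only after the other results were seen. Other genes stood apart from every tissue even with the embryo arrays averaged; they are named after their values were seen. ODC1, the first enzyme of polyamine synthesis, read 457 ± 67.6 (SD, n = 3) in embryos and 23.5 ± 13.1 (SD, n = 7) in tissues, and rose by 2.47 log2 (limma adjusted p = 0.00248 with averaged arrays). LGALS3, a galectin, rose by 2.44 (adjusted p = 0.0124), and CTAG2, an antigen of germ cells and tumours, by 2.29 (adjusted p = 0.045), reading 601 in embryos and 68.6 in tissues. NASP, a histone chaperone, rose by 1.98 (adjusted p = 0.0151), and CSE1L, a nuclear export factor, by 1.77 (adjusted p = 0.0391). Both JARID2 probe sets, for a partner of the Polycomb complex, were higher in embryos, at 1071 and 873 against 136 and 232. Only the first of them, which rose by 2.49, passed with averaged arrays. MBNL2, a splicing regulator related to MBNL1, fell by 1.77 (adjusted p = 0.0377).

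Among adult tissues, where each value is from 1 array, metabolic lists had their own profile. Glycolysis genes averaged 1.03 log2 above the adult mean in muscle and 0.55 in heart. Fatty acid oxidation genes averaged 0.99 in kidney, 0.77 in liver and -0.95 in brain, and the 3 embryo arrays averaged -0.64, -0.67 and -0.79. MHC genes averaged 1.16 in spleen and 0.52 in lung, -0.84 in brain and -0.49 in muscle, and -0.71, -0.80 and -0.85 on the embryo arrays. Ribosomal protein genes averaged 0.54 in spleen, 0.44 in lung and 0.42, 0.41 and 0.34 on the embryo arrays, and -0.62 in brain.

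Spleen was the adult tissue closest to embryos, ahead of lung by 0.0711 in mean rank correlation. A hypothesis was that genes of the growth and housekeeping lists shared by embryos and spleen set this lead. Leaving out 583 probe sets of all process lists, fatty acid oxidation and complement among them, kept 0.950 of the lead (95% bootstrap interval 0.566 to 1.12 over 500 draws). Leaving out the 100 probe sets that add most to it kept 0.355, a fall that was certain because they were picked for it in these data. On these arrays, the 0.950 argues against the genes of these lists as the source of most of the lead. The interval resamples probe sets, while the lead rests on 1 spleen and 1 lung array. Growth genes outside the lists and a relation to cell types of the spleen stay open as untested.

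Each of the 8 groups was also set as 1 sample against the other 7 with limma. The embryo mean had 78 probe sets called, liver 18, heart 1 and the other tissues 0, so 0 tissues had more calls than embryos. At an unadjusted p under 0.05 the embryo mean had 609 probe sets, liver 543, muscle 431, brain 355, heart 314, lung 211, spleen 182 and kidney 175. With the first, the second or the third embryo array alone in place of the mean, the embryo again had the most calls. The order was therefore not set by averaging, but the spread came from the other 7 groups alone. The filter was also uneven between groups. It tested probe sets bright on the embryo arrays alone, and none bright in 1 tissue alone. By the restriction rule, which does not use this filter, 182 probe sets were restricted to liver, 91 to brain and 26 to embryos. Muscle (40), heart (33) and lung (31) also exceeded embryos, while spleen (11) and kidney (10) did not. That rule was stricter for embryos, where all 3 arrays had to pass the percentile and their mean was used, so these counts are unlike. With each group counted as 1 sample and this filter, the limma calls cannot decide whether the embryo is the most distinct of the 8 groups. Nor can the restricted counts.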
